A study of Mus musculus with 4 samples.

How the data were processed

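Allele-specific RNA-seq was analysed in 4 libraries of female mouse epiblast stem cells (EpiSCs), 1 library for each combination of Smchd1 genotype (+/+ or MD1/MD1) and Xist mutation (XistdeltaA/+ or Xist1lox/+). Total RNA was made into stranded mRNA libraries, per the labels' protocols. The submitters' processing notes name the genome build mm9 and the tools Cufflinks 2.2.1 and Cuffdiff, with no role or order. The aligner, the list of strain variants and the gene annotation are not given in the sources used here.

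The deposited table lists 22686 genes, of which 952 lie on the X chromosome. For each gene and library the authors deposited 3 values, per the file headers. The first is the count of allele-assigned reads, which are reads that cover a strain variant and so are a part of the reads of a gene. The second is the fraction of those reads that carry the paternal allele, which the authors give for genes with at least 10 such reads apart from 3 genes per library. Multiplied by the read count, this fraction gave whole numbers of paternal reads for 100% of the values, within 1e-06. The third deposited value is FPKM, and any scaling of it between libraries is not given in the sources used here. A further 6 columns of per-sample values belong to no sample of this series and were not used. Starts in the table count from 0, as checked on 1097 olfactory receptor genes. End minus start was divisible by 3 for 84.0% of them, against 7.47% with 1 added. Coordinates are given here counted from 1, in mm9. The reference annotation at hand is of another build and none of its coordinates were used.

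Allele-assigned reads summed to 7826600 in the +/+ XistdeltaA/+ library, 8008500 in MD1/MD1 XistdeltaA/+, 7822217 in +/+ Xist1lox/+ and 7301034 in MD1/MD1 Xist1lox/+. Each MD1/MD1 library was set against the +/+ library with the same Xist mutation. The paternal share of X-linked genes was pooled over reads and given per gene, for genes with at least 20 allele-assigned reads in all 4 libraries, with exact Clopper-Pearson intervals at 95%. A gene counted as expressed from the paternal allele at a share of 10% or more. Fisher's exact test (two-sided) compared paternal and maternal reads per gene within each pair, and a normal test of the difference of log odds ratios compared both pairs, each with Benjamini-Hochberg adjustment over the X-linked genes compared. The fold measures and counts were fixed before the data were examined, while the read tests were added afterwards.

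Total expression was analysed as log2(FPKM + 1) for 11471 genes with a mean FPKM of at least 1, so that ratios of low genes are understated. limma 3.58.1 with a trend fitted Smchd1 genotype plus Xist mutation, 2 libraries against 2, with 1 residual degree of freedom and Benjamini-Hochberg adjustment. That residual is the difference of the Smchd1 effect between both Xist backgrounds, so the model treats it as noise. The plan named edgeR's quasi-likelihood test for a file that holds counts. The deposited counts cover strain variants only and leave out genes without such variants, so limma on FPKM was kept as the main test and edgeR 4.0.16 on the allele-assigned read counts was run as an added alternative. This was settled with both results already seen, and both counts are printed together in the report. Genes at least 2-fold higher or lower in both Xist backgrounds were counted by a fixed rule of size. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Medians of lists were set against 10000 random lists of the same size matched on mean expression.

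The cross leaves some autosomal regions with maternal-type alleles alone. Autosomes were split into 257 windows of 10 Mb, and a window was called maternal-type only where the median paternal share of its genes was under 5%. This window step was chosen after the data had been seen. Named genes followed a rule fixed before the data were examined. It took Smchd1 and Xist, the 15 X-linked genes with the largest rise of the paternal share in both backgrounds and the 5 with the largest fall. For total expression it took the 10 highest and 10 lowest genes past 2-fold in both backgrounds, since fewer than 10 passed the model, up to 5 each way for the Xist mutation, and the members past the rule or the 4 highest expressed of each gene list. Other named genes are said to be chosen after their values were seen. A gene that the rule would name is not reported here.

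Fisher's exact test on shares and the Smchd1 contrasts of limma and edgeR were tried on simulated data with known changes, and the other tests were not. Fisher's exact test called 56.0% of 100 genes with a simulated rise of 5 points in both backgrounds, 90.0% of 100 with 15 points and 0% of 141 unchanged genes. These simulated reads varied by counting error alone, so the 0% does not cover false calls from spread between libraries. For the Smchd1 contrast of 11471 genes, limma called 12.0% of 50 genes at a log2 change of 1, 86.0% at 2, 96.0% at 3 and 98.0% at 4, with 8 false calls among 11271 unchanged genes. edgeR on 10724 genes called 16.0%, 80.0%, 94.0% and 98.0%, with 15 false calls among 10524. Alternatives covered the read minimum, the share threshold, the pseudocount, the filter on FPKM, quantile normalization, the covariate, left-out libraries, allele-assigned reads in place of FPKM, and windows whose alleles matched. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.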

Results

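Gene expression and its split between parental alleles were measured in 4 libraries of EpiSCs, pluripotent cells derived from the epiblast of female mouse embryos described as deficient for SmcHD1 or not. SmcHD1 is a chromatin protein that acts on the inactive X chromosome. Cells carried Smchd1 +/+ or MD1/MD1 together with either of 2 Xist mutations, XistdeltaA/+ or Xist1lox/+. Xist is the long noncoding RNA that coats the inactive X. There were no replicates: each combined genotype had 1 library, so differences within a pair have no replicate check. The libraries held 7826600, 8008500, 7822217 and 7301034 allele-assigned reads (+/+ XistdeltaA/+, MD1/MD1 XistdeltaA/+, +/+ Xist1lox/+ and MD1/MD1 Xist1lox/+). Intervals are exact Clopper-Pearson intervals at 95% and cover counting error only.

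Smchd1 (mm9, chromosome 17, 71693834 to 71824683) was lower in both MD1/MD1 libraries. Its FPKM was 27.0 in +/+ and 6.68 in MD1/MD1 with XistdeltaA/+, and 20.9 and 5.98 with Xist1lox/+. The log2 ratios were -1.87 and -1.65, and the adjusted p from limma over all genes was 0.173. The paternal share of Smchd1 reads was 51.2% and 52.4% in the +/+ libraries, and 0% and 0.532% in the MD1/MD1 libraries. The 10 Mb window that holds Smchd1 carried maternal-type alleles alone in both MD1/MD1 libraries and both alleles in the +/+ libraries. The share therefore follows the region and is not particular to Smchd1. Xist (X chromosome, 100655712 to 100678572) went the other way. Its FPKM was 12.1 in +/+ and 38.3 in MD1/MD1 with XistdeltaA/+, and 10.5 and 28.9 with Xist1lox/+, with an adjusted p of 0.266 from limma. Xist reads were paternal at 99.5%, 99.9%, 99.9% and 99.8% in the 4 libraries, in the order given above. The paternal X is therefore the chromosome that transcribed Xist in every library.

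The first comparison asked how much of X-linked expression came from the paternal X with and without SmcHD1. The paternal share was higher in both MD1/MD1 libraries. Over 341 X-linked genes it was 4.52% (4.42 to 4.62) in +/+ and 14.8% (14.66 to 14.98) in MD1/MD1 with XistdeltaA/+. With Xist1lox/+ it was 5.13% (5.02 to 5.24) in +/+ and 13.5% (13.4 to 13.7) in MD1/MD1. Xist reads made up part of this difference. Without Xist, Ftx and Jpx the share of the other 338 genes was 2.59% and 9.23% with XistdeltaA/+, and 3.44% and 9.40% with Xist1lox/+. The differences were then 6.65 and 5.96 points, against 10.3 and 8.40 points with all genes. The mean of gene shares with equal weight differed by less, 4.66 and 4.42 points.

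**Figure D1:**
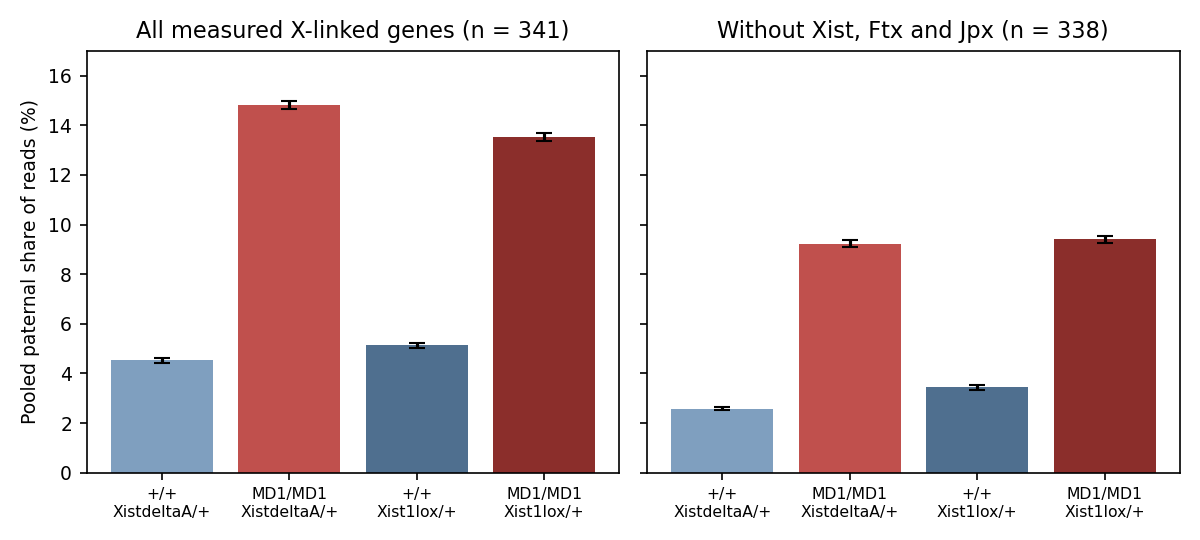
Pooled paternal share of allele-assigned reads (%, y axis) of X-linked genes in each of the 4 libraries, with 95% Clopper-Pearson intervals, for all 341 genes (left) and for 338 genes without Xist, Ftx and Jpx (right). Both MD1/MD1 libraries lie above their +/+ library, at 14.8% and 13.5% on the left and 9.23% and 9.40% on the right.

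The median gene had a paternal share of 0% and 0.228% in the +/+ libraries and 3.55% and 3.57% in MD1/MD1. Autosomal windows of 10 Mb that carried maternal-type alleles alone were measured as the background. They were picked by a median share under 5% in the same library, so a low share there is partly set by that choice. Inside such windows the pooled paternal share was 0.172% and 0.281% in the +/+ libraries, and 0.884% and 0.359% in the MD1/MD1 libraries. FPKM attributed to paternal alleles, summed over the 338 genes, was 4.23 times higher in MD1/MD1 with XistdeltaA/+ and 3.49 times higher with Xist1lox/+. The FPKM attributed to maternal alleles was 0.944 and 0.984 times that of +/+.

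Several genes with almost no paternal reads in +/+ had paternal shares of over 15% in both MD1/MD1 libraries. Ogt, which encodes the enzyme that attaches N-acetylglucosamine to nuclear and cytoplasmic proteins (98835390 to 98879690), had paternal shares of 0.0748% and 0.254% in the +/+ libraries. In MD1/MD1 its shares were 32.5% (30.2 to 34.9) and 32.7% (30.3 to 35.1). Ercc6l, a helicase acting in mitosis, had 0 paternal reads of 616 and 602 in +/+, which allows up to 0.597% and 0.611%, and shares of 25.6% and 27.7% in MD1/MD1. Idh3g, a subunit of mitochondrial isocitrate dehydrogenase, had 0 paternal reads of 1273 and 991 in +/+ and shares of 26.7% and 25.2% in MD1/MD1. Shroom2 went from 0.133% and 0.297% to 25.6% and 24.2%. Shroom4, with 34 to 142 reads, had no paternal read in +/+ and shares of 33.8% and 29.8% in MD1/MD1. Taf1, Ikbkg, Ndufa1 and Chic1 had shares of 24.7%, 18.4%, 19.3% and 16.9% in MD1/MD1 XistdeltaA/+ and of 19.7%, 20%, 16.9% and 21.4% in MD1/MD1 Xist1lox/+. In +/+ the highest share among these 4 genes was 0.350%, for Ikbkg. Otud5, Mmgt1, Kantr, Yipf6, Klhl4 and Ftx completed the 15 genes with the largest rise in both pairs. Of these 6, Klhl4 and Ftx were already at 21.2% and 16.9% in the +/+ XistdeltaA/+ library. Klhl4 did not pass Fisher's exact test in the Xist1lox/+ pair (adjusted p = 0.0714), on 56 and 28 reads.

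Of the 341 genes, 15 and 24 were at 10% paternal or more in the +/+ libraries and 81 and 88 in the MD1/MD1 libraries. In both MD1/MD1 and neither +/+ library, 49 genes reached 10%, where independent lists of the 70 and 68 genes gained in each pair would share 14.0. In the opposite direction 1 gene was lost in both pairs. At a threshold of 5% the gained genes numbered 89, and at 20% they numbered 11. By Fisher's exact test with Benjamini-Hochberg adjustment, 122 genes had a higher and 7 a lower paternal share in both pairs. That test compares those libraries, not the conditions. The differences in both pairs had a Spearman correlation of 0.746 across genes, which are not independent replicates.

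The share fell in both pairs for 7 genes by the same read test. Fundc1, a mitophagy receptor (17133695 to 17149423), went from 23.1% and 21.2% to 10.6% and 13.3%. Pak3 went from 7.75% and 7.29% to 0%. Firre and Tmem164, named after their values were seen together with Gabra3, Pcyt1b and Armcx2, went from 3.67% and 3.37% to 0.601% and 0.370%, and from 3.19% and 5.90% to 0.270% and 0.191%. Firre is a long noncoding RNA gene. Among the 5 largest falls, Atg4a, Klf8 and Foxr2 did not pass in both pairs at 37 to 89 reads a library.

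Genes known to escape X inactivation had high paternal shares in both genotypes. Of 11 measured, 7 were at 10% or more in both +/+ libraries and 9 in both MD1/MD1 libraries. Kdm6a was at 46.5% and 49.2% with XistdeltaA/+ and at 48.8% and 43.0% with Xist1lox/+. Ddx3x was at 34.8% and 35.6%, then at 33.0% and 35.5%. Kdm5c was at 33.4% in both XistdeltaA/+ libraries and at 25.4% and 31.05% in the Xist1lox/+ pair. Utp14a and Ftx passed the read test in both pairs, also when adjusted over the list alone, where 2 genes passed. Utp14a was at 4.96% and 1.19% in +/+ and at 17.3% and 16.0% in MD1/MD1. Of 6 measured genes of the X inactivation centre, 3 passed in both pairs, and 3 did so adjusted over the list alone. These were Ftx, Chic1 and Rlim, the last going from 0.935% and 0.314% to 5.57% and 7.40%.

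The position along the X was described in 10 Mb windows. Both pairs had a positive median difference in 12 of 14 windows with at least 5 genes. The windows with the highest share of genes past the read test in both pairs lay at 30 to 40 Mb (12 of 18 genes) and at 20 to 30 Mb (7 of 13). Between 40 and 70 Mb few genes passed, 2 of 20, 3 of 18 and 1 of 9 in the windows in turn. Hprt in this interval, named after its value was seen, had shares of 1.01% and 1.06% in MD1/MD1.

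**Figure D2:**
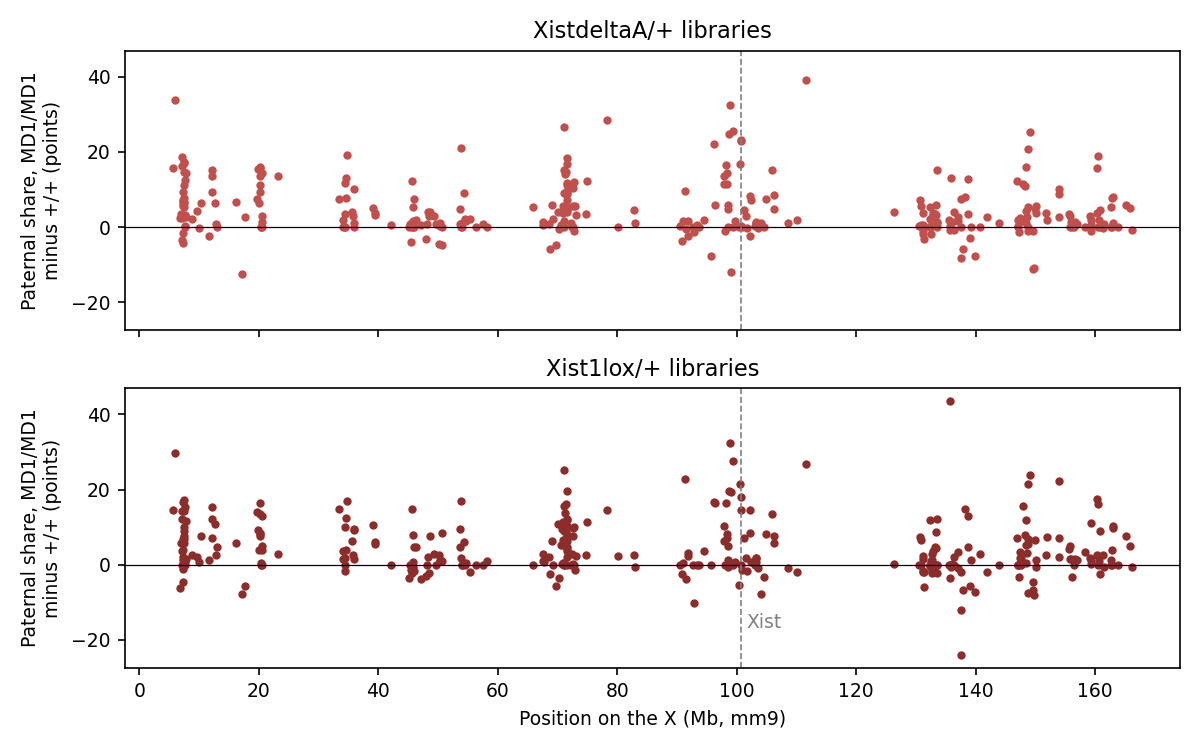
Difference in paternal share (percentage points, y axis, MD1/MD1 minus +/+) of each of 341 X-linked genes against its position on the X (Mb, mm9, x axis), for XistdeltaA/+ (upper) and Xist1lox/+ (lower), with Xist marked by the dashed line. Points lie mostly above 0 in both panels, with 256 and 232 genes higher and 49 and 74 lower.

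The next comparison was of the total output of X-linked genes. The median log2 FPKM ratio of 383 X-linked genes was -0.055 with XistdeltaA/+ and 0.070 with Xist1lox/+. Autosomal genes had medians of -0.047 and 0.0019. Among 10000 random autosomal lists matched on expression, the X median lay at the 29.3 percentile with XistdeltaA/+ and at the 100 percentile with Xist1lox/+. With genes of a mean FPKM of at least 0.1 the first median turned to 0.0095. The 49 genes gained in both pairs had median log2 ratios of 0.16 and 0.23, and their shares alone would give 0.24 and 0.22 with an unchanged maternal allele. The other 292 genes had medians of -0.078 and 0.046.

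Across all genes the comparison of Smchd1 genotypes gave few calls. With limma, Rpl10 and Ehd3 were higher and Htr7 and Rpl10a lower in MD1/MD1, 4 of 11471 genes at an adjusted p under 0.05, and 374 had an unadjusted p under 0.05. Htr7, a serotonin receptor gene (chromosome 19), had FPKM of 32.8 and 32.7 in the +/+ libraries. It was listed at 0 in MD1/MD1 XistdeltaA/+ and had 0.0185 in MD1/MD1 Xist1lox/+ (log2 ratios -5.08 and -5.05, limma adjusted p = 0.00561). Its allele-assigned reads were 100% and 99.9% paternal in the +/+ libraries. The window that holds Htr7 carried maternal-type alleles alone in both MD1/MD1 libraries. An effect of Smchd1 genotype on Htr7 therefore cannot be told apart from the absence of the paternal allele there. Ehd3, which acts in endosomal transport (chromosome 17, 74154181 to 74181433), had 1.48 and 2.64 in +/+ and 32.3 and 29.8 in MD1/MD1 (log2 ratios 3.75 and 3.08, limma adjusted p = 0.0477). Ehd3 was not called by limma with a pseudocount of 0.1 or after quantile normalization, nor by edgeR. Rpl10 had log2 ratios of 4.05 and 4.66 (limma adjusted p = 0.0110) and Rpl10a of -5.28 and -4.90 (limma adjusted p = 0.00561). These ribosomal protein genes have processed copies elsewhere in the genome, so their FPKM is uncertain, and the allele-assigned reads gave -0.49 and 0.52 for Rpl10 and 0.78 and 0.30 for Rpl10a, the latter on 4 to 13 reads a library. edgeR on allele-assigned reads called 5 genes, 3 higher (U2af2, Ifitm2 and Atp5h) and 2 lower (Tdg, which shares its entry with Gm9855, and Htr7). The 3 higher genes had 0 allele-assigned reads in both +/+ libraries and 1149 to 1930 in MD1/MD1, and Tdg had 747 and 769 against 1 and 0. Allele-assigned reads were dropped by Smchd1 genotype for 8 genes, by Xist mutation for 3 and by the remaining split of the libraries for 2. Apart from Htr7 the genes called by edgeR had near-equal FPKM, with log2 ratios between -0.32 and 0.44. No gene passed limma without a filter on low FPKM, where 567 had an unadjusted p under 0.05. With Smchd1 genotype as the only term, limma called 6 genes over all 4 libraries, 3 higher and 3 lower. Leaving out a library leaves 1 in a group, so counts of such fits are not given.

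By the fixed rule of size, 15 genes were at least 2-fold higher and 13 at least 2-fold lower in MD1/MD1 in both Xist backgrounds. Independent lists would share 1.99 and 0.783. Higher genes included Olfr293, an olfactory receptor gene listed at 0 in both +/+ libraries and at 5.85 and 11.05 in MD1/MD1, and Rab38, a small GTPase at 0.716 and 0.790 against 4.77 and 4.19. Tom1, 5730507C01Rik, Gm3020, Pisd-ps1 with Pisd-ps3, and Pisd-ps2 were higher too, of which the last 3 entries can share reads with near-identical copies and are uncertain. Lower genes included Ly6g6c (6.43 and 4.79 against 0.437 and 0.493), Socs5, a suppressor of cytokine signalling (14.0 and 10.3 against 4.88 and 3.95), and Dpp6, an accessory subunit of potassium channels (4.72 and 7.53 against 1.40 and 2.29). E030030I06Rik and the X-linked Trap1a were lower, the latter at 36.7 and 70.2 against 9.47 and 17.5. Rps28 and Mup6 were lower as well and belong to families with copies. Of the 28 genes 9 lay on chromosome 17, which held 5.13% of genes tested. Of 24 autosomal genes 15 lay in windows where the paternal allele was present in libraries of only 1 Smchd1 genotype, as 14.2% of tested genes did. In windows whose alleles matched within both pairs, and on the X, 11 genes were left. The remaining pairing set MD1/MD1 Xist1lox/+ over +/+ XistdeltaA/+, and MD1/MD1 XistdeltaA/+ over +/+ Xist1lox/+. It gave 81 higher and 12 lower genes, against 15 and 13 in the Smchd1 pairing. Both of its ratios are still MD1/MD1 over +/+, so it is not a background free of Smchd1 genotype.

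**Figure D3:**
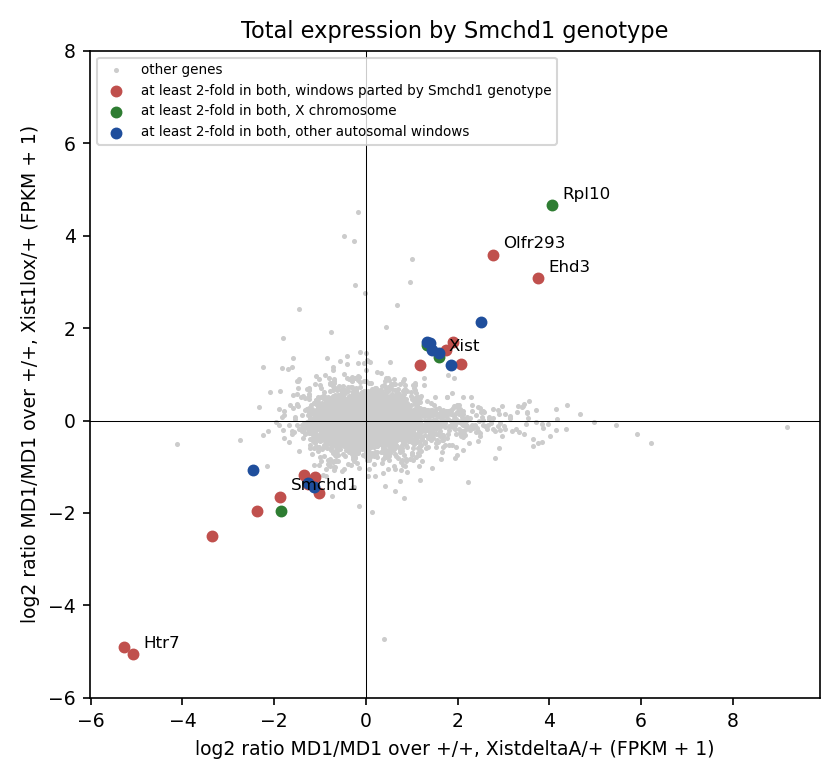
Log2 ratio of FPKM + 1, MD1/MD1 over +/+, with XistdeltaA/+ (x axis) and with Xist1lox/+ (y axis), for 11471 genes, with the 28 genes at least 2-fold changed in both coloured by location. Most of the coloured autosomal genes, 15 of 24, lie in windows where the paternal allele was present in 1 Smchd1 genotype only, among them Htr7, Ehd3 and Smchd1. Unlike Htr7 and Smchd1, Ehd3 was higher where the paternal allele was absent.

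The XistdeltaA/+ pair differed more widely than the Xist1lox/+ pair, with 448 against 51 genes at least 2-fold higher in MD1/MD1 and 209 against 43 lower. The fibroblast list, which marks feeder cells, had a median log2 ratio of 1.36 with XistdeltaA/+ (100 percentile) and 0.16 with Xist1lox/+ (97.3 percentile). The percentile did not set this list apart. Primed epiblast and other imprinted genes also lay at 100 with XistdeltaA/+, and p53 targets at 100 with Xist1lox/+. Col1a1 was at 9.31 and 30.7 FPKM with XistdeltaA/+ and at 14.2 and 12.7 with Xist1lox/+. Col1a2 was at 6.34, 26.7, 11.7 and 11.1, Acta2 at 6.10, 14.3, 9.68 and 6.71, and Thy1 at 8.15, 13.9, 8.05 and 11.3 in the same order. Of the 8 members of the fibroblast list, 5 were at least 2-fold higher in the first pair and 0 in the second, and 0 passed limma. camera gave an adjusted p of 0.000548, and the adjusted p was 0.656 with an estimated correlation. Macrophage genes, a list chosen after the values were seen, went along with them. Lyz2, the macrophage lysozyme, was at 0.384 and 799 FPKM with XistdeltaA/+ and at 274 and 247 with Xist1lox/+.

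**Figure D4:**
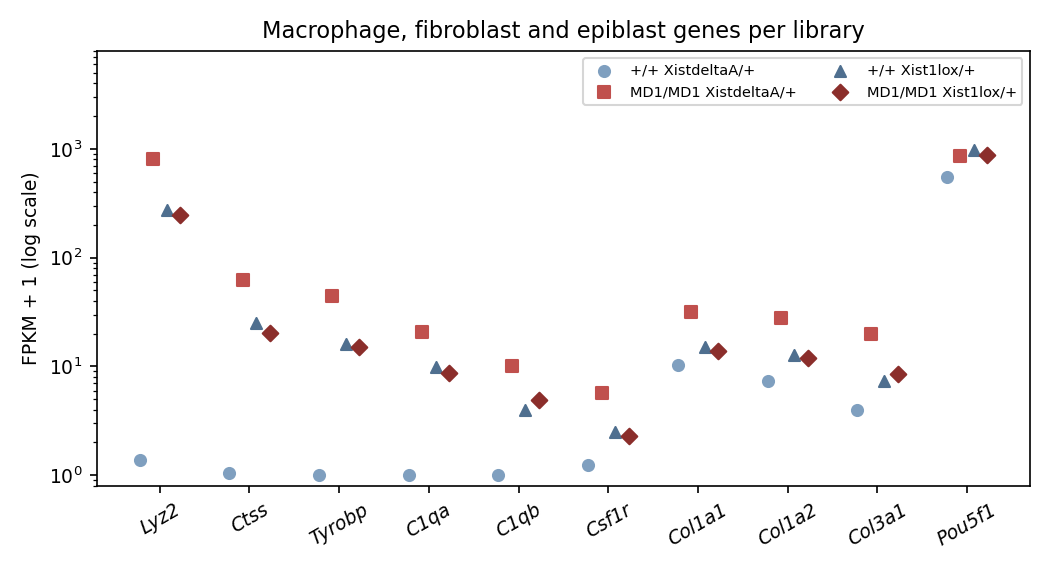
FPKM + 1 (log scale, y axis) of 6 macrophage genes, 3 fibroblast collagen genes and the epiblast gene Pou5f1 in each of the 4 libraries. Macrophage genes lie lowest in +/+ XistdeltaA/+, where Lyz2 is at 0.384 FPKM, and highest in MD1/MD1 XistdeltaA/+, where it is at 799.

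Lists of other cell states did not pass. The median log2 ratios of the 11 primed epiblast genes were 0.43 and 0.065, at the 100 and 93.3 percentiles (camera adjusted p = 0.149, and 0.656 with an estimated correlation). Among them Pou5f1 was at 551 and 856 FPKM with XistdeltaA/+ and at 984 and 873 with Xist1lox/+, Dnmt3b at 144, 320, 242 and 268, Zic2 at 96.2, 68.9, 79.7 and 88.2, and Nanog at 87.1, 56.1, 90.0 and 94.2. Of 3 measured trophoblast genes the medians were 0.83 and -0.20 (camera adjusted p = 0.938), with Krt7 at log2 ratios of 0.83 and -1.67, Tfap2c at -0.68 and -0.20, and Hand1 at 2.17 and -0.10. Fewer than 3 members were measured of the naive pluripotency list (Klf2 and Klf4, medians 0.19 and -0.21), the mesendoderm list (Gsc and Eomes, 0.023 and 0.15), the primitive endoderm list (Dab2, 0.077 and 0.099), the neural list (Nes, 0.76 and 0.069) and the germline list (Tex19.1, 0.48 and -0.23). Of the Hox and Rhox lists 0 members had a mean FPKM of at least 1, and 0 genes of the male list are in the table.

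Of the imprinted lists, the Snrpn cluster had medians of 0.37 and 0.11 over 5 members (camera adjusted p = 0.00633, and 0.656 with an estimated correlation). Ndn, a gene of this cluster known to be expressed from the paternal allele, was at 2.77 and 14.8 FPKM with XistdeltaA/+ and at 5.43 and 13.9 with Xist1lox/+, and was the 1 member past the test adjusted over the list alone. Snrpn, sharing its entry with Snurf, had log2 ratios of 0.37 and 0.047, Ube3a of -0.057 and 0.28, and Atp10a of 0.19 and -0.12. All 5 members lie in windows where the paternal allele was present in 1 Smchd1 genotype only. So do both measured members of the Igf2r list, Igf2r (log2 ratios 0.18 and 0.091) and Slc22a3 (-0.30 and 0.88), with medians of -0.063 and 0.48. The 20 other imprinted genes had medians of 0.37 and -0.41, at the 100 and 0 percentiles (camera adjusted p = 0.938), among them Gnas (-0.63 and -0.40), Grb10 (-0.45 and -0.089), Phlda2 (0.80 and 0.13) and Meg3 (0.82 and -0.42).

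The X inactivation centre list had medians of 0.21 and 0.28 over 5 genes (camera adjusted p = 0.00633, and 0.656 with an estimated correlation), and fry gave an adjusted p of 0.0182. Xist was its 1 member past the test adjusted over the list alone. Rlim had log2 ratios of 0.67 and 0.28, and Ftx of 0.21 and 0.23. The 10 escape genes had medians of 0.032 and 0.12 (camera adjusted p = 0.182), with Ddx3x at 0.46 and 0.39, Pbdc1 at -0.027 and -0.022, Utp14a at 0.35 and 0.10, and Eif2s3x at -0.30 and 0.13. The 31 Xist partners and silencing factors had medians of -0.056 and 0.10 (camera adjusted p = 0.938). Among them Smchd1 alone passed adjusted over the list alone, while the 4 highest expressed members were Trim28 (0.13 and -0.014), Hnrnpu (0.12 and 0.042), Dnmt3b (1.15 and 0.15) and Hnrnpk (0.033 and 0.016). The 5 measured clustered protocadherins, reported targets of SmcHD1, had medians of 0.20 and -0.23 (camera adjusted p = 0.938), with Pcdhgc3 at -0.43 and -0.23, Pcdhga11 at 0.20 and 0.21, Pcdhga10 at 0.34 and 0.0092, and Pcdhgb7 at -0.14 and -0.47. These share exons, which makes their values uncertain. The 12 p53 targets had medians of -0.23 and 0.34 (camera adjusted p = 0.329), with Bax at 0.11 and -0.12, Pmaip1 at 0.66 and 0.48, Cdkn1a at 0.28 and 0.51, and Ccng1 at -0.54 and 0.55.

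The last comparison was between the Xist mutations with Smchd1 genotype held. Xist itself differed little between them, with log2 ratios of -0.18 in +/+ and -0.39 in MD1/MD1 (Xist1lox/+ over XistdeltaA/+). By the rule of size 3 genes were higher in both Xist1lox/+ libraries, 1810044D09Rik (1.26 and 1.26), Frmd4b (1.22 and 1.25) and Hist1h3c (1.22 and 1.28), and 7 were lower, where independent lists would share 0.642 and 3.49. Frmd4b was at 6.47 and 4.33 FPKM with XistdeltaA/+ and at 16.4 and 11.7 with Xist1lox/+. The lower genes included Gpr137b, a lysosomal membrane protein gene, at 22.5 and 21.3 with XistdeltaA/+ and 3.15 and 3.39 with Xist1lox/+, and Gm6251, Alms1-ps2, Ninj2 and Rmrp, of which Gm6251 and Alms1-ps2 can share reads with copies. limma called 0 of 11471 genes, with 368 at an unadjusted p under 0.05, and edgeR on allele-assigned reads called 0.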

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

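All tests of explanations in this part were chosen, with their limits, after the results they bear on had been seen, and the test of feeder RNA with XistdeltaA/+ took 3 forms, of which an interval over reads argued against it, an interval over genes left it open and the last is given here.

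The first pattern is the higher paternal share of X-linked genes in both MD1/MD1 libraries. Misassigned alleles would raise autosomal genes in windows with maternal-type alleles alone about as often, but there at most 6.95% of genes rose by 2 points or more in a pair, against 54.0% and 51.3% of X-linked genes. Windows whose median share reached 5% in either library of a pair were left out, which limits this test. Whether the dropping of reads by Smchd1 genotype, counted at 8 genes, bears on the X share was not tested. A fraction of cells with a wholly active paternal X would lift every gene, yet 18 of 169 genes with at least 200 reads in both MD1/MD1 libraries (10.7%, narrowly over the limit of 10% that was set) had upper limits under 2% in both, which counts against it as the whole cause and leaves a smaller fraction open. In the Xist1lox/+ pair, 20 macrophage and fibroblast genes had a median log2 ratio of -0.081 (-0.15 to 0.13). Of these, 12 were macrophage genes from a list written with its values known. The 8 fibroblast genes, from a list fixed beforehand, had a median of 0.16. Both medians fell short of the log2 rise of 1.45 needed, which argues against RNA from feeder cells in this pair. With XistdeltaA/+ it is argued against as the whole cause, because of 6 X-linked genes with at least 200 reads that were doubled or more in MD1/MD1, and above both Xist1lox/+ libraries, 4 (66.7%) had upper limits under the share needed, which is the 9.23% of all genes times the new part of each gene's FPKM (Bgn was at 0.169% of 1778 reads, Timp1 at 0% of 711, Cybb at 0% of 229), although Pim2 and Mid1 did not and the interval over genes of an earlier set of 7, pooled at 6.70%, holds 9.23% (1.47 to 11.4%); Smchd1 genotype stays open, and an exact permutation test of 2 libraries against 2, which cannot give a two-sided p under 0.333, does not bear on it.

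The second pattern is the set of autosomal genes at least 2-fold changed with Smchd1 genotype in both Xist backgrounds. Strain haplotypes that differ between genotypes are a candidate explanation: without Smchd1, 14 of 23 genes (60.9%) lay in windows where the paternal allele was present in 1 genotype only, against 14.2% of genes tested (permutation p = 0.0052, 10000 rotations of the windows along the genome). Of the 14 genes, 12 were higher where the paternal allele was present, and 7 of the 8 with a share were at least 70% paternal there. The 12 include Rpl10a and Rps28, whose FPKM is uncertain. Ehd3 and Dpp6 went the other way and were higher where the paternal allele was absent. The other 9 of the 23 genes are not covered by the haplotype explanation. An effect of Smchd1 genotype remains open for those 9 and for the 14, where genotype and haplotype go together.

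The third pattern is a group of X-linked genes near Xist with a higher paternal share in both Xist1lox/+ libraries, all chosen after their values were seen. Efnb1, Kif4, Snx12, Hmgn5, Rps6ka6 and Chm (96331469 to 110299124) were at least 10 points higher there than with XistdeltaA/+ in both Smchd1 genotypes, and 0 genes were lower by as much. Chm was at 98.1% and 96.3% against 4.05% and 5.85%. Strain variants flanking the Xist1lox allele may account for them, since their starts spanned 13.8 Mb with Xist inside, less than random sets of 6 genes (permutation p = 5e-05, 100000 sets), although the other 35 of 41 genes there, Ogt, Ercc6l and Taf1 among them, did not differ by as much. Added transcription of the paternal alleles is argued against for Chm and Hmgn5, whose maternal reads, scaled by library total, were 0.0181 and 0.189 times those with XistdeltaA/+ in +/+ and 0.0372 and 0.348 times in MD1/MD1, below the 2.5 percentile of other X-linked genes (0.409 and 0.556), and it cannot be told apart for the other 4, among which Kif4 and Rps6ka6 were at 0.511 and 0.336 in +/+ but at 0.850 and 0.818 in MD1/MD1, inside that spread, and where the median log2 FPKM ratio was -0.11 in +/+ and fell short of the rise the shares would give by 0.45 (-0.14 to 1.08 over genes) and in MD1/MD1 by 0.20 (-0.0024 to 0.70).

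Differences between the Xist backgrounds in the change with Smchd1 genotype were tested on reads for X-linked shares, and 7 genes had an adjusted p under 0.05. This read test covers counting error only and compares those libraries, not the conditions. Not all of the 7 are named in this report. For those that are, the change in points with XistdeltaA/+ minus that with Xist1lox/+ was 5.46 for Yipf6, -2.43 for Utp14a, 3.32 for Kif4, 6.29 for Snx12 and 0.894 for Hmgn5. The last 3 belong to the third pattern, and their +/+ shares already differed, at 0%, 0.416% and 0% with XistdeltaA/+ against 21.9%, 20.6% and 34.1% with Xist1lox/+. The test compares log odds, so that a small difference in points can pass where the +/+ library was near 0.

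Other results moved in opposite directions in the 2 backgrounds, each with 1 library per genotype, and these differences were not tested. The median log2 ratio with XistdeltaA/+ minus that with Xist1lox/+ was 0.40 for naive pluripotency genes, 1.03 for trophoblast genes, -0.16 for Xist partners and silencing factors, 0.43 for clustered protocadherins, -0.55 for the Igf2r cluster, 0.78 for other imprinted genes, 0.70 for germline genes, -0.56 for p53 targets and -0.12 for the total expression of X-linked genes. Among cell state markers the difference was 0.81 for Pou5f1, -0.62 for Zic2, -0.69 for Nanog, 0.48 for Klf4, -0.56 for Gsc, 0.31 for Eomes, 2.505 for Krt7 and 2.28 for Hand1. For the feeder genes Col1a1, Col1a2 and Acta2 it was 1.77, 1.99 and 1.58. It was -0.43 for Eif2s3x, 0.15 for Trim28, -0.34 for Ube3a, 0.31 for Atp10a, -1.18 for Slc22a3, 1.25 for Meg3, 0.70 for Tex19.1, 0.23 for Bax and -1.09 for Ccng1.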

How the results depend on the processing

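Alternatives with allele-assigned reads in place of FPKM, edgeR, matched windows, 5 Mb windows, or without the 6 genes near Xist were chosen after seeing the data. The cause of each change below was not tested unless the setting itself shows it. The rise in pooled paternal X share was above 0 in all settings tried, at 6.65 and 5.96 points without the Xist region genes and at 4.66 and 4.42 points with equal weight per gene. Genes gained in both pairs numbered 89 at a 5% and 11 at a 20% threshold. limma's count for Smchd1 genotype was 0 without a filter and between 9 and 24 with a library left out, where Smchd1 genotype was the only term and the lone library is assumed to vary like the pair. Genes at least 2-fold changed in both backgrounds numbered 50 with a pseudocount of 0.1, 98 at 1.5-fold, 7 at 4-fold, 63 by allele-assigned reads and 11 in matched windows and on the X. Lists passing camera numbered 0 with an estimated correlation. The median of total X expression was -0.065 and 0.078 with a pseudocount of 0.1, 0.0095 (opposite in sign) and 0.045 at a mean FPKM of at least 0.1, and -0.062 and 0.078 at 5. Rpl10 turned to -0.49 by allele-assigned reads. The other 22 alternatives of answers to a comparison were within 1.5 times the main count or the main value's counting error, and of those for single genes and lists 57 stayed on their side and 5 no longer passed. A close count need not mean the same genes. For Smchd1 genotype limma called 4 genes and edgeR 5, and Htr7 alone was called by both. Depth limits genes with few variants: at 23 reads a share of 0 allows up to 14.8% (Car5b). The main limma model pairs libraries by Xist mutation, and with 1 library per combined genotype there is no replicate number to block on.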

Other observations

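All tests in this part were chosen after the results had been seen, and the macrophage list was written with its values known.

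Macrophage genes had a larger median ratio with XistdeltaA/+ than any list fixed beforehand, a rank that writing the list with its values known could give by itself. Of 12 genes 11 were at least 2-fold higher in MD1/MD1 than in +/+ with XistdeltaA/+ (median log2 ratio 3.94), and 0 differed 2-fold with Xist1lox/+ (median -0.11). Ctss was at 0.0436 and 61.5 FPKM with XistdeltaA/+ and at 24.0 and 19.3 with Xist1lox/+, and Gpnmb at 0.140, 84.5, 24.5 and 17.3. Tyrobp and the complement gene C1qa were listed at 0 in +/+ XistdeltaA/+ and had 43.0 and 19.5 in MD1/MD1 XistdeltaA/+. Spp1, the osteopontin gene, was at 90.5, 1195, 328 and 384. On the X, the matrix protein gene Bgn had paternal shares of 0%, 0.169%, 0% and 0.115%, and Timp1, a protease inhibitor gene, of 0%, 0%, 0.235% and 0.743%. Flna, a gene of the actin cytoskeleton whose FPKM was 80.8 and 121 with XistdeltaA/+, had 0.126%, 9.02%, 0.196% and 8.81%. On autosomes, paternal shares in MD1/MD1 XistdeltaA/+ differed widely, with 41.7% of 24 reads for Tyrobp, 26.6% for Spp1, 18.6% for Cd68, 5.86% for Csf1r, 5.49% for Ctss, 0.436% for Gpnmb, 0.302% for Laptm5, 0.223% for Mpeg1 and 0.0265% for Lyz2. Spp1 was at 28.7%, 27.9% and 28.5% in the other libraries. In the same order Cd68 was at 61.0%, 35.8% and 30.9%, so its share was lowest in MD1/MD1 XistdeltaA/+. Ctss and Csf1r had no share in +/+ XistdeltaA/+. With Xist1lox/+ Ctss was at 4.81% and 5.73%, and Csf1r was above its 5.86% in both libraries. Tyrobp was at 66.7% of 12 reads in +/+ Xist1lox/+. Gpnmb, Laptm5, Mpeg1 and Lyz2 were at 1.15% or less wherever they had a share. The collagen-modifying enzyme gene Plod2 went the opposite way, at 247 and 36.2 with XistdeltaA/+ and at 258 and 192 with Xist1lox/+.

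The rise of the paternal share may come in runs of neighbouring genes. Over 13 windows of 10 Mb with at least 10 genes, the percent of genes up by 2 points or more in both pairs had a standard deviation of 17.6 points, against a median of 10.3 for labels shuffled along the X (p = 0.001, permutation test of 100000 shuffles). It was lowest at 50 to 60 Mb (16.7%) and highest at 20 to 30 Mb (69.2%). Between 40 and 70 Mb, an interval picked from these values, 9 of 47 genes rose, against 136 of 294 elsewhere.

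Xist FPKM and the paternal X share were both higher in MD1/MD1, which might follow if part of the +/+ cells had lost the inactive X. The odds of a paternal read of escape genes would then rise by the same factor as the pooled odds, which rose 3.83 times with XistdeltaA/+ and 2.91 times with Xist1lox/+. Over the 10 measured escape genes with a paternal read the median odds ratio was 1.32 (0.974 to 3.08 over genes) and 1.82 (1.12 to 2.59), which argues against this as the whole cause. Kdm6a, Ddx3x, Kdm5c and Mid1, the deepest covered along with Utp14a, had ratios between 0.792 and 1.32, while Utp14a (3.98 with XistdeltaA/+ and 15.3 with Xist1lox/+), Ftx (3.24 and 2.74), Jpx (3.08 and 2.45) and 1810030O07Rik (2.16 and 2.11) rose more. Earlier forms of the test used the 7 genes at 10% or more in both +/+ libraries, and the one on ratios of shares (1.06 and 1.37 against 3.57 and 2.73) had left the Xist1lox/+ pair open.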
